A study of Mus musculus with 20 samples.

How the data were processed

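Genomic DNA of 20 thymic lymphomas was compared with DNA from the ear of the same mouse on 2-colour arrays for comparative genomic hybridisation, which measure the relative copy number of DNA at each probe. The mice were female B6C3F1, an F1 hybrid strain, and developed the tumours after 4 weekly exposures of 1.6 Gy that began at 4 to 5 weeks of age. Per the labels, the series title, design text and sample names give carbon ions as the radiation, while the treatment protocol field names X-rays. The samples are described here as carbon-ion samples, and this conflict stays open. All 20 samples form 1 group, and no unirradiated or X-ray tumours were analysed here.

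The deposited values are log2 ratios of lymphoma (Cy5) over ear (Cy3) for 40666 probes on each array, and per the submitters' processing notes they came from Agilent Feature Extraction 10.5.1.1. Dye normalisation, probe filters and genome build are not given in the sources used here. All arrays had 1 dye orientation, so a dye effect of a probe is not removed by averaging. The log base, the centring and the direction were read from the values. Among segments of 50 or more probes the level below 0 with the highest density was -0.83, and the level above 0 was 0.54. On a log2 scale these correspond to 1.13 and 2.91 copies against 2, on a natural log scale to 0.872 and 3.43 copies, and on a log10 scale to 0.296 and 6.93 copies. The lost level is as near to 1 copy on the natural log scale as on log2, but only log2 puts both levels between 2 and a change of 1 copy, where admixed normal DNA would move them. The lowest segment of any array lay at -6.91 and the highest at 1.53. Loss of both copies has no lower bound on a log scale, so the deep levels mark the lymphoma as the numerator, the direction that the dyes in the labels also give. The medians of the deposited arrays ranged from -0.08 to 0.06, so the deposited centring was close to, but not exactly, the median. Each array was centred on its median before analysis. Between 3 and 195 probes per array had no value. The noise SD per array, from differences of neighbouring probes, was 0.11 ± 0.01 (SD, n = 20), and no depth applies to arrays, whose precision is limited by their number.

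The files used here do not pair the probe IDs with genes or positions, and no gene, chromosome or coordinate is therefore given. The ordering of probes was taken from the numbers in their IDs, a choice made after seeing the data. In 2 blocks of numbers, called number series 1 (12187 probes) and number series 2 (27291 probes), the mean correlation of neighbouring probes over the 20 arrays was 0.798 and 0.845. After shuffling it was -0.00152 and 0.00507. Of the 10 recurrent regions, 7 appeared at nearly the same percentage of the number range in both series, which were therefore taken as 2 separate sets of probes for the same DNA. The match allowed a distance of 0.35% of the range, a setting chosen after seeing the data, and narrow regions need not overlap. Loss region 1 lay at 34.33% to 34.34% in series 1 and at 34.10% to 34.12% in series 2. Levels of the 2 series at 2000 even places correlated with a mean r of 0.626 over the 20 arrays (0.356 to 0.864). The same call was made at 97.7% ± 2.16 of places (SD, n = 20), where chance would give 86.2% ± 9.19 because most places have no call. Of places called in either series, 67.0% ± 25.7 had the same call (SD, n = 20), with a range from 11.7% to 90.8%. In tumour 31 the gained extent was 2.28% in series 1 and 0.0711% in series 2. A further 1188 probes had no place and entered only the test of single probes. Percentages of the number range are not percentages of the genome, because the numbers are unevenly filled. The 2 series are technical repeats on the same array, and n counts tumours throughout.

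Each series was segmented on each array by a recursive search for the interval whose mean differed most, as in circular binary segmentation. A split was kept when it lowered the residual sum of squares by over 4 times the noise variance times the natural log of the number of probes. A segment was called gained or lost when it held at least 5 probes and its median was at or beyond 0.25 or -0.25. Touching called segments of 1 direction were joined into 1 stretch. Chromosome ends were not known and each series was segmented as a whole. A stretch may therefore run over more than 1 chromosome, which affects the counts and lengths of stretches. A level at or below -1.5 was termed a deep loss, a limit set after seeing the data. Recurrence was tested by placing the stretches of every tumour at a random offset along the number range 1000 times. A probe was recurrent when the number of called tumours exceeded the 95th percentile of the maximum over these placements. The overlap was computed exactly after a first version on a grid of places missed short stretches in the simulated data. Recurrent stretches of at least 5 probes were joined over gaps under 0.02% of the number range and matched between the series within 0.35%, settings chosen after seeing the data.

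Single probes were tested against 0 with limma 3.58.1 (intercept model, empirical Bayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. Segmentation and permutation used Python 3.11.15, numpy 2.4.6, numba 0.67.0, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9. The steps were checked on simulated data. In 5 simulated arrays of 27291 probes with the median noise, inserted segments of 5, 20 or 100 probes at levels of -0.9, 0.5 and -3 were recovered in 100% of cases, with 0 false stretches. The simulated noise was independent between probes, without the slow offsets along the probe order of the real arrays. Over probes in no called segment, the SD of these offsets ran from 0.0247 to 0.114 per array. Gains below 0.5 were not simulated, so the 0 false stretches do not bound false gains on the real arrays. Of 100 random placements of the lost stretches, 3 gave a region above the limit. These placements were drawn in the same way as those of the test, so they check the computation alone. They cannot show whether the uneven filling of the number range affects recurrence. In a simulation of the limma test with 40269 probes, 34.5% of 200 probes shifted by 0.1 and 85% of 200 probes shifted by 0.4 were recovered, with 14 false calls among 253. That simulation held no offsets shared between arrays either.

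Before the data were examined, the tests, thresholds, alternatives and rules for named items were fixed. The gene lists fixed then (tumour suppressors and oncogenes of T-lineage tumours, antigen receptor loci, DNA damage response and thymocyte development), the test of chromosomes and the rules for naming genes could not be applied without gene names. Probes took the place of genes. The rule named the 5 largest falls and rises past the threshold with 1 probe per run of neighbours, taken here as places within 0.35% of the number range, and the first 2 of each direction are given. The alternatives were other centring, thresholds, minimum lengths and penalty, robust empirical Bayes, array weights, a sign-flip permutation test, leaving out each tumour, and others added later. No other columns of per-sample values were used.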

Results

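Copy number was profiled in 20 thymic lymphomas of B6C3F1 mice that had been exposed to carbon ions, each against the ear of the same animal. The design asks which DNA segments are gained or lost in these tumours and how often. Each array carried 40666 probes, of which 39478 could be placed along the 2 number series. Regions are named by direction and by order along the number range, since genes and positions were not used here.

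Every tumour had lost DNA, and every tumour had at least 1 gained stretch in each series. On average gains covered more of the number range than losses, though not in every tumour. Probes fill that range unevenly, so this does not show that more probes or more DNA were gained than lost. In series 2, gains covered 5.77% ± 4.90 of the number range (SD, n = 20) and losses covered 1.73% ± 1.23 (SD, n = 20). Series 1 gave 6.26% ± 4.92 for gains and 1.55% ± 1.12 for losses (SD, n = 20). The number of lost stretches per tumour was 12.9 ± 3.17 in series 1 and 13.5 ± 4.73 in series 2, and that of gained stretches was 8.40 ± 7.34 and 8.90 ± 6.50 (SD, n = 20). Over all tumours and both series there were 526 lost and 346 gained stretches, with the 2 series counted apart. A threshold of 0.15 in place of 0.25 raised these counts to 925 and 995.

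The extent of change differed widely between tumours. Tumour 28 had the largest gained extent (14.2% in series 2) and also the largest lost extent (5.75%). Tumours 24, 30 and 35 had gained 13.6%, 13.1% and 12.4% of the series 2 range. In tumour 1 the gained extent was 0.417% and the lost extent 0.0356%, the smallest lost extent of the 20. Tumour 14 had the smallest gained extent, 0.0423%, with a lost extent of 2.41%. Segments of 50 or more probes were termed broad, whatever their share of the number range, with deep losses left out. The level of broad losses was -0.80 ± 0.13 (SD, n = 20) and that of broad gains 0.45 ± 0.12 (SD, n = 19, as tumour 14 had no broad gain). Broad losses can thus be narrow along the range: tumour 1 had a broad loss level of -0.87 within its lost extent of 0.0356%.

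**Figure D1:**
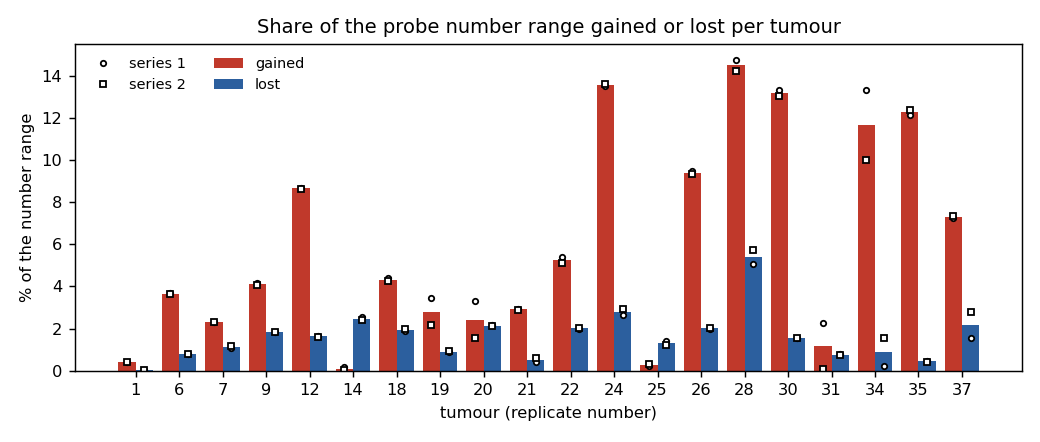
Bars give, for each of the 20 tumours, the percentage of the probe number range called gained or lost, as the mean of the 2 number series, and symbols give each series. In series 2 the gained extent runs from 0.0423% in tumour 14 to 14.2% in tumour 28.

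Recurrent losses fell into 7 regions and recurrent gains into 3. At a threshold of 0.15 there were 15 and 20, and without centring there were 7 and 1. Of the 7 loss regions and 3 gain regions, 6 and 1 were found in both number series. The limit was 5 tumours for losses and 7 for gains, and in random placements the maximum ranged from 3 to 6 and from 4 to 9 tumours. The highest observed counts were 20 tumours for losses in both series, and 12 and 11 tumours for gains in series 1 and series 2.

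**Figure D2:**
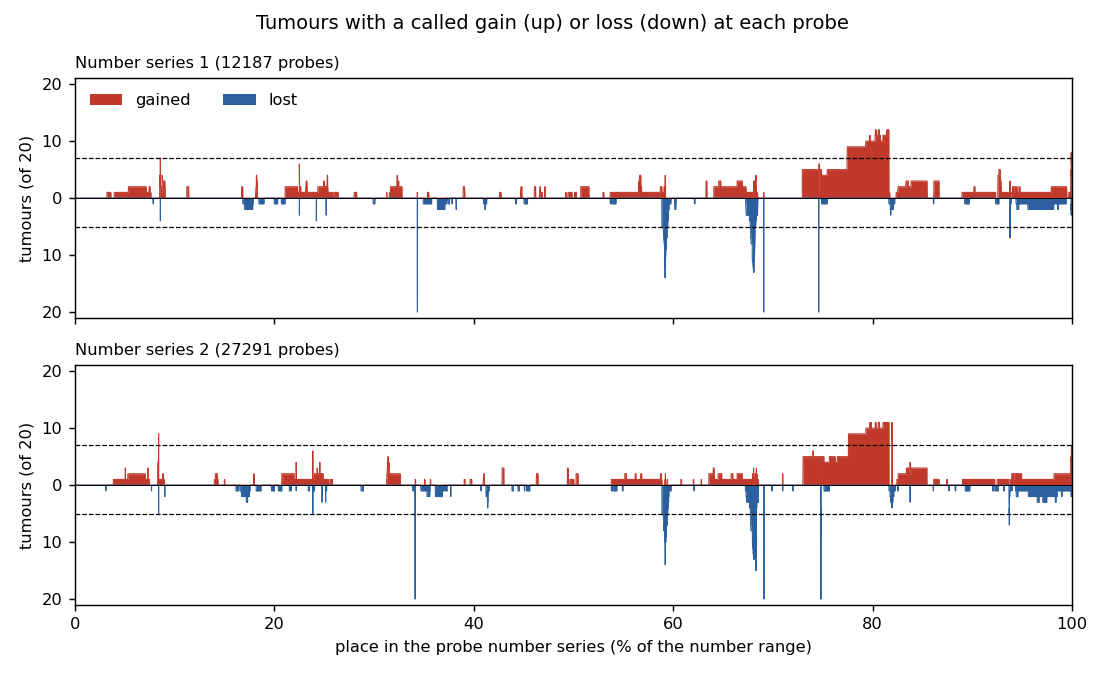
The vertical axis gives the number of tumours, of 20, with a called gain (up) or loss (down) at each probe, and the horizontal axis the place in each number series as a percentage of the number range. Dashed lines mark the limits of 7 tumours for gains and 5 for losses, and 3 narrow losses reach 20 tumours in both series.

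Loss regions 1, 5 and 6 were lost in 20 of 20 tumours in both series, mostly at levels far below that of 1 lost copy. In loss region 1, at 34.1% of the series 2 range, the level at the peak was -3.50 ± 1.41 (SD, n = 20), and 17 tumours had a deep loss. Tumours 1, 19 and 26 lay at -0.87, -0.91 and -1.01, near the level of 1 lost copy, and tumours 6 and 9 at -1.92 and -1.64. In loss region 5, at 69.1%, the level was -3.54 ± 0.77 (SD, n = 20). It was a deep loss in 19 tumours, and tumour 30 lay at -0.85. In loss region 6, at 74.8%, the level was -4.15 ± 1.1 (SD, n = 20), again with a deep loss in 19 tumours, and tumour 30 was near the level of 1 lost copy in series 2 but at -3.38 in series 1. Series 1, with other probes, gave -3.64 ± 1.51, -4.04 ± 0.92 and -3.65 ± 0.67 for the 3 regions (SD, n = 20).

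The ends of these losses differed between the 3 regions, and where a region held more than 1 lost stretch they are those of the longest. In loss region 1 the upper end lay within 5 probes of 1 place in 20 of 20 tumours, while the lower end fell at 5 different places in series 2. In 13 tumours the same stretch held both a part near the level of 1 lost copy and a deep part. Loss region 5 held 2 separate lost stretches in each tumour in series 2, and 2 or 3 in series 1. The longest held 31 probes in the median tumour of series 2, with 16 tumours sharing the lower end and 19 the upper end within 5 probes. Loss region 6 had 6 different lower ends and 3 upper ends in series 2, 18 tumours shared the upper end within 5 probes, and 18 tumours held both kinds of level. In 3 tumours (12, 26 and 30), over 15 of the 30 probes on each side of this loss were called gained in both series, a count made after seeing the data.

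Loss regions 2 and 3 were lost in part of the tumours, at levels near that of 1 lost copy and over stretches of very different length. Loss region 2, at 59.0% to 59.4% of the range, was called at its peak in 14 tumours in each series. The levels of these 14 lay between -0.80 and -0.51 in series 2, the other 6 tumours lay between -0.01 and 0.28, and no tumour had a deep loss at the peak. Some tumours had more than 1 lost stretch in the region, and the longest stretch that reached the peak held from 79 to 3986 probes in series 2. Loss region 3, at 67.8% to 68.2%, was called in 13 tumours in each series, with levels between -0.77 and -0.51 in series 2 and 113 to 475 probes in the longest stretch that reached the peak. Over all 20 tumours the peak level was -0.45 ± 0.40 in loss region 2 and -0.35 ± 0.41 in loss region 3 (SD, n = 20). A call anywhere in the region, in either series, was made in 15 tumours for loss region 2 and 14 for loss region 3, and 10 tumours had both.

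Loss region 7, at 93.7%, was called in 7 tumours in both series, and 4 of the 7 had a deep loss. Tumours 7, 21, 22 and 35 lay at -3.80, -2.82, -2.07 and -2.20 in series 2. The region covers 67 probes in series 2, and the longest stretch that reached the peak ranged from 50 to 194 probes. Of the 7 tumours with this loss, 6 also had a call in loss region 3 and 3 had one in loss region 2. Loss region 4 was a short stretch of 8 probes at 68.3%, just beyond loss region 3, that was found in series 2 alone. It was called at the peak in 15 tumours, with a deep loss in 9, and in 8 tumours with a minimum of 10 probes in place of 5. The peak held 2 probes, so these deep levels rest on 2 probes per array. The longest stretch that reached the peak ranged from 5 to 475 probes, with a median of 5.

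Gain region 2 was the most frequent broad gain. It ran from 77.6% to 81.6% of the range, over 929 probes of series 2 and 357 of series 1, and was called in 12 tumours in series 1, in 11 in both series and in 13 in either. Tumour 31 was called in series 1 only, and tumour 7 in series 2 only, over 5 probes with a peak level of 0.16. At its peak the level was 0.46 ± 0.29 in series 1 and 0.40 ± 0.28 in series 2 (SD, n = 20), and the called tumours of series 1 ranged from 0.31 to 0.85. The longest stretch of each tumour that reached some part of the peak covered from 0.214% to 7.03% of the range in series 1, with a median of 4.16%. Of the tumours with this gain, 10 also had a call in loss region 3 and 8 in loss region 2.

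Gain regions 1 and 3 were short and passed the limit in series 2 alone. With a limit from series 1 alone, 6 tumours, series 1 had a gain in 7 tumours at 8.55%, near gain region 1, and none near gain region 3. With limits from each series alone, a further gain of 6 probes near the upper end of the range was past the limit in both, in 8 tumours in series 1 and 7 in series 2. Gain region 1, at 8.38%, covered 7 probes and was called in 8 tumours, with levels between 0.33 and 0.47. The other 12 ran from -0.29 to 0.27, and 19 of 20 tumours lay above 0. These levels are medians over the probes at the peak, whereas calls rest on the median of the whole segment. No tumour was called there at a threshold of 0.4, and 6 were, under the limit of 7, with either other centring. Gain region 3, at 82.0%, covered 21 probes and was called in 11 tumours, in 4 at that threshold and in 8 with either other centring. Without centring, only 1 gain region was recurrent. The peak levels of gain region 3, medians over 4 probes, ran from -0.90 to 1.26.

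**Figure D3:**
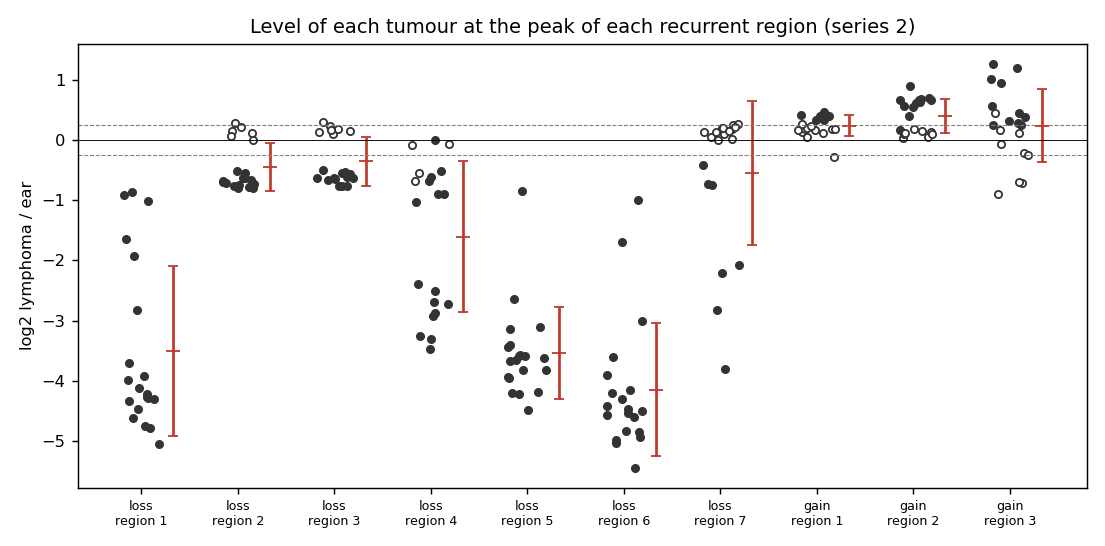
Each point is the level (log2 lymphoma over ear) of 1 of the 20 tumours at the peak of a recurrent region in series 2, filled where the tumour had a call in that region, and red bars give the mean ± SD of all 20. Loss regions 1, 5 and 6 lie mostly below -1.5, whereas the called tumours of loss regions 2 and 3 lie between -0.80 and -0.51.

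At single probes, limma found 27756 of 40666 probes shifted from 0 at the adjusted threshold, 14772 lower and 12984 higher. Most shifts were small, with a median size of 0.18 on the log2 scale. A mean change of at least 0.25 was reached by 8971 of them, 6811 lower and 2160 higher, a limit added after seeing the data. Of the 275 placed probes with a mean at or below -1.5 and past the threshold, 273 lay in a recurrent loss region. The largest falls were at A_67_P07801201, in loss region 5, by -5.12 ± 1.37 (SD, n = 20, lower in 20 of 20 tumours, limma adjusted p = 1.53e-11), and at A_67_P02851367, in loss region 6, by -5.10 ± 1.16 (SD, n = 20, lower in 20 of 20, limma adjusted p = 1.59e-12). The largest rises were at A_67_P08417965, in gain region 2, by 0.71 ± 0.31 (SD, n = 20, higher in 20 of 20, limma adjusted p = 1.79e-08), and at A_67_P09257779, at 95.6% of the range, by 0.67 ± 0.63 (SD, n = 20, higher in 17 of 20, limma adjusted p = 0.000217). Gain region 2 was called in 13 tumours in either series, so the rise at A_67_P08417965 does not mark a gain in all 20. The files used here do not pair these IDs with genes. Probes in no called segment of any tumour also passed the test in large number (10519 of 13778 when fitted alone), so a call at a single probe does not mark a gained or lost copy. Over these 13778 probes, each array correlated with the mean of the other arrays at r from 0.670 to 0.922, so their offsets were largely shared.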

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

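The probe order, the overlap and joining of regions, the counting of touching segments apart, the rotation along the probe rank, the 0.25 minimum, the number series alone and the tests of subsets of probes were chosen after the data were seen. Of 130 values under an alternative other than a left-out tumour, 108 stayed within 1.5 times the reported value, and so did all 140 values with 1 tumour left out. Many of the 130 are counts of tumours at peaks fixed by the main calls. Among them are loss regions 1, 5 and 6, whose levels lie beyond every threshold tried. The pooled share therefore says little about the numbers of stretches and regions. Loss regions 1, 5 and 6 were called in 20 tumours, loss region 2 in 14 and loss region 7 in 7 under each of 7 alternatives for centring, thresholds, lengths and penalty, loss region 3 in 13 to 14 and gain region 2 in 11 to 14. Without 1 tumour, recurrent losses numbered 7 to 8, recurrent gains 2 to 4 and shifted probes 27049 to 28046.

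A threshold of 0.15 gave 925 lost and 995 gained stretches, 15 recurrent losses and 20 recurrent gains, and a threshold of 0.4 gave 212 gained stretches. With a minimum of 3 probes there were 811 lost stretches, with 10 probes 228 gained ones, and with a doubled penalty 218 gained ones. Counting touching segments apart gave 2605 losses and 687 gains, by construction. Without centring, 1 gain was recurrent. With its own limit, series 1 alone gave 6 recurrent losses and 3 gains, and series 2 alone 8 and 4. Rotation along the probe rank gave 6 recurrent losses and 4 gains. Gain region 1 was called in 14, 0 and 4 tumours with a threshold of 0.15, of 0.4 and with the doubled penalty, gain region 3 in 4 at 0.4, and loss region 4 in 8 with 10 probes. A mean change of at least 0.25 left 8971 probes (6811 lower, 2160 higher), and a fit of probes in no called segment gave 10519 (5061 lower, 5458 higher), both by construction from fewer probes. For the other changes the cause was not tested. Not run, for want of gene names, positions or a genome, were the chromosome and listed-gene tests, gene summaries, filters on probes per gene, antigen receptor probes left out and the GC correction.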

Other observations

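All tests in this part were chosen after the results they measure had been seen, and several were revised after a first outcome.

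The losses called in all 20 tumours were set against a probe response that is the same on every array. In loss regions 1 and 6 the losses had at least 5 different ends on the more varied side in series 2. In loss region 5 the stretch over the probes lost in all 20 was followed. It reached past the commonest lower end by over 5 probes in the same 4 tumours (22, 24, 25 and 37) in both series. A response alike on every array, as the whole cause, forbids both, and in tumour 30 loss region 5 lay at -0.85 and -1.07 in the 2 series. The match between the series depends on the limit of 5 probes. Tumours 1, 6 and 18 also started below the commonest end in series 1, within that limit, but at the commonest end in series 2. As a hypothesis, rearrangement of gene segments, which every T-lineage cell makes, may underlie loss regions 1 and 6. The pattern looked for was 1 shared end and 1 varied end, and at least 18 of 20 tumours shared the more common end in series 2. That pattern was chosen after these ends had been seen, so the match does not test the hypothesis. Loss region 5 leaves it open too. There 16 tumours shared even the less common end in series 2. The longest stretch had 4 lower ends in series 1, but only 2 when the stretch over the probes lost in all 20 was followed.

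Broad gains came at intermediate levels in part of the tumours. If broad losses are of 1 copy, lowered by admixed normal DNA alone, they imply 0.35 to 0.57 for 3 copies, depending on the tumour. Admixed normal cells, or compression of an array's ratios, would act alike on every change of an array, whereas a gain in a part of the tumour cells would give gains of different size on 1 array. Pairs of broad gains were therefore chosen in 1 series, 1 over 0.1 below the implied level and 1 not, differing by over 0.15 and over 3 SD of the slow offsets, and measured at the same places in the other. Only 3 tumours had such a pair over at least 1% of the range, all chosen in series 1, with a median measured difference of 0.29 that was above its limit in 2 of them, and series 2 gave none. Without that length, 8 tumours had a pair in either series and 4 in both, with differences chosen to be large. The deepest segment of each tumour left 0.83% to 11.8% of the DNA. Normal cells that keep both copies there can make up no more. In tumours 34 and 37, with broad losses at -0.46 and -0.51, 3.11% and 3.21% were left, so their implied levels are uncertain. Other tumours show this too, such as 21, 22 and 26, with broad losses at -0.68, -0.73 and -0.76. They had 2.88%, 3.94% and 5.05% left. All implied levels assume admixture alone, so the pairs and counts based on them share this uncertainty. The small remainders argue against normal cells that keep both copies as the whole cause of the intermediate levels. They do not bound normal cells that have lost the same DNA. Such admixture, compression and a gain in part of the tumour cells cannot be told apart with so few pairs measured apart from their choice.

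The short gain regions 1 and 3, past the limit in series 2 alone, were set against an offset shared by all arrays and against a gained copy in part of the tumours. In gain region 3, 3 tumours lay at or below -0.25 in the median of the 4 probes at the peak. For these 4 probes, that argues against a shared offset as the whole cause. Of the 20 tumours, 15 in gain region 1 and 6 in gain region 3 lay over 0.1 above 0 and over 0.1 below their own level for 3 copies. Near that level or above were 3 tumours in gain region 1 (28, 34 and 37) and 8 in gain region 3. These implied levels are uncertain, above all in tumours 34 and 37. A gained copy can therefore not be told apart in either region. In gain region 1, 19 of 20 tumours lay above 0, but tumour 22 lay at -0.29, where a shared offset alone would put all 20 above 0. A shared offset that is larger on some arrays may contribute to gain region 1, where rho with the size of the offsets was 0.582, a relation too loose to decide.

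The level of gain region 1 was related to the size of the slow offsets on each array with Spearman rho = 0.582 (two-sided permutation p = 0.00831, adjusted p = 0.0198 over 3 relations, n = 20). Pearson r was 0.396 (permutation p = 0.0825, adjusted p = 0.19), and 0.397 without the 2 tumours whose offset size was farthest from the median. Tumour 22, at -0.29 in gain region 1, was not among those left out. For gain region 3, rho was 0.328 (permutation p = 0.159, adjusted p = 0.159) and r was 0.289 (permutation p = 0.218, adjusted p = 0.218), or 0.384 without the 2 farthest in offset size. The levels of the 2 regions were related to each other with rho = 0.553 (permutation p = 0.0132, adjusted p = 0.0198) and r = 0.356 (permutation p = 0.126, adjusted p = 0.19), or 0.617 without the 2 farthest in the level of gain region 1.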
